A study of Homo sapiens with 47 samples.

How the data were processed

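The series held 47 samples, of which 24 were RNA-seq libraries, 13 ChIP-seq samples against a factor or histone mark, 9 ChIP inputs and 1 nucleosome and methylation map. The expression tables of the RNA-seq libraries and the 6 lists of ZFX and ZNF711 peaks were analysed here, and the histone mark, RNA polymerase, input and nucleosome samples were not analysed here. ZFX ChIP had 2 samples each in C42B, HCT116, HEK293T and MCF7 and 1 in PrEC, and ZNF711 ChIP had 2 in MCF7. Per the labels' protocols, cells received 100 nM of an siRNA pool, were transfected again 24 h later and were harvested after a further 24 h, and the transfection reagent differed between C42B and MCF7. The amount of each siRNA in the siBoth libraries is not given in the sources used here. RNA libraries were made with a stranded mRNA kit, per the labels' protocols. Groups were taken from the sample labels.

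The submitters' processing notes name STAR, BWA, Partek 3, BSMAP, MACS2 and the hg19 build, without saying which tool made which file. The deposited expression tables hold 1 value per gene and library. These are an expression signal scaled by the authors within each library, since the 75th percentile lay between 36.37 and 38.12 in all libraries and sums ran from 775705 to 865816. The exact unit and scaling are not given in the sources used here. Genes were listed in all libraries of an experiment or in none, with no value of 0. Low values were tested for whole multiples of 1 read. With a tolerance of 0.1 between 44.7% and 80.0% came out whole, below the 95% needed to recover reads, so the depth is unknown and no count model was used. The planned design assumed raw counts and a count model, and was replaced by limma on the log2 scale because of the unit of the files. Peak lists are in the narrowPeak layout, and each deposited peak carries a score, a fold enrichment ratio, and -log10 p and -log10 q values of the authors. The score was 10 times the -log10 p cut to a whole number, as the deposited values show. The background of the fold enrichment is not given in the sources used here. Gaps in the peak numbers show that some peaks were removed, for reasons not given in the sources used here. How replicate ChIP samples were turned into 1 list per cell type and factor is not given in the sources used here, and peak scores and folds are used here to rank peaks within a list. Scaling to an equal upper quartile hides a change shared by most genes, and peaks of unequal width share bases more or less easily.

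For each experiment, values were transformed as log2(value + 1), genes with a mean value of at least 1 over the libraries of the fit were kept, and limma 3.58.1 with an intensity trend was fitted in R 4.3.3 with 1 mean per group. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The C42B and single-knockdown MCF7 fits used their 6 libraries and the 4-group fit its 12 libraries. The 11 contrasts were siZFX against control in 3 experiments, siZNF711 and siBoth against control, siBoth against each single knockdown, siZFX against siZNF711, the interaction, and the differences of the siZFX effect between C42B and single-knockdown MCF7 and between the MCF7 experiments. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Replicate numbers were checked for pairing. In single-knockdown MCF7 the deviations of the 3 same-numbered pairs correlated at 0.12 to 0.23, above the limit of 0.1, so a fit with the replicate number as a block was run beside the main one. Differently numbered pairs there correlated at -0.3 to 0.23, so the numbers may not mark true pairs.

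The 29 gene lists were fixed before the data were examined. They covered estrogen response, androgen response, G1/S and DNA replication, G2/M and mitosis, p53 targets, cholesterol synthesis, the ATF4 amino acid response, ER chaperones and the unfolded protein response, interferon response, NF-kB genes, hypoxia, immediate early genes, epithelial, mesenchymal, immune and endothelial, and intestinal markers, cytosolic ribosomal proteins, ribosome biogenesis, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, lysosome, glycolysis, core housekeeping, spliceosome, proteasome, extracellular matrix remodelling, PI3K AKT MAPK components, apoptosis regulators and replication-dependent histones. Lists with at least 5 tested members were tested with camera, which compares the members with the other genes, at a preset correlation of 0.01. Camera with an estimated correlation and fry, which tests whether the members move on balance 1 way, were run beside it. Named genes followed a rule also set in advance, with its limit on expression moved to a mean log2(value + 1) of at least 3. It took the targets, the 10 highest and 10 lowest called log2 changes without overlap between groups in each knockdown against control, the 5 highest and 5 lowest in other contrasts, up to 4 members with the smallest adjusted p per list, the 10 highest and lowest mean changes shared by the 3 siZFX experiments, and the 3 peaks with the highest score per list. Clone names, pseudogenes, and peaks on chromosomes 8, Y and M were left out. The limit on expression was not applied to the targets and the list members.

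Peaks were compared with bedtools 2.31.1, with an overlap of at least 1 bp. All peaks lay within the chromosomes of the GRCh37 reference, whose annotation gave transcript starts, exons and gene positions. A promoter peak is a summit within 1000 bp of a start. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Of the 55765 gene symbols, 33182 matched a current and 1889 an older symbol, 378 were ambiguous and 20316 matched none, but 90.3% to 92.1% of tested genes were mapped. Peaks at changed genes were tested with 2-sided Fisher's exact tests in Python 3.11.15 with scipy 1.17.1, adjusted over 18 tests. Tables were handled with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures drawn with matplotlib 3.10.9.

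Alternatives were median-of-ratios scaling, no filter, a pseudocount of 0.25, the replicate block, the 2 compared groups alone, leaving out each library, other windows, gene sets and overlaps for peaks, the top 50% of each list, and strata of expression, of GC content and length of the transcript, and of GC content and CpG count within 500 bp of the canonical start. The limma steps were tested on simulated data with 100 genes changed by each of 0.5 and 1 on the log2 scale. They recovered 88% and 99% for C42B (13846 genes), 72% and 97% for single-knockdown MCF7 (13698 genes), 73% and 95% for siZFX in 4-group MCF7 (14337 genes), and 56% and 92% for the interaction (14337 genes). Positions relative to starts were recovered for 15805 of 15805 simulated positions.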

Results

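Binding of the zinc finger transcription factors ZFX and ZNF711 was mapped by chromatin immunoprecipitation sequencing (ChIP-seq) in human cells, and gene expression was measured by RNA sequencing after their knockdown with small interfering RNA (siRNA). C42B is a prostate cancer line, MCF7 a breast cancer line, HCT116 a colon cancer line and HEK293T an embryonic kidney line, while PrEC are primary normal prostate epithelial cells. The RNA part held 24 libraries in 3 experiments with 3 replicates per group. In C42B and in a first MCF7 experiment, called single-knockdown here, siRNA against ZFX (siZFX) was set against a non-targeting control (siCtrl). The other MCF7 experiment, called 4-group here, added siRNA against ZNF711 (siZNF711) and against ZFX and ZNF711 together (siBoth). The ChIP part gave 6 peak lists, 1 for ZFX in each of the 5 cell types and 1 for ZNF711 in MCF7. Values per gene were the authors' scaled expression values, which summed to 775705 to 865816 per library with a 75th percentile of 36.37 to 38.12. Sequencing depth behind them is unknown. The labels speak of triplicate transfections without naming separate cultures, so p-values measure the spread between these samples, which may be technical.

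ZFX itself fell in each experiment that targeted it. The ZFX gene (X chromosome, 24167290 to 24234372, plus strand, GRCh37) stood at 16.58 ± 0.302 after siZFX and 47.98 ± 1.34 in control C42B cells (mean ± SD, n = 3), which is 34.6% of control. In single-knockdown MCF7 it stood at 7.729 ± 0.698 and 39.82 ± 1.26, or 19.4% of control. In the 4-group experiment ZFX was 35.16 ± 2.9 in control, 9.598 ± 0.448 after siZFX, 9.901 ± 0.709 after siBoth and 37.14 ± 3.03 after siZNF711. The limma log2 changes against control were -1.48 in C42B, -2.23 in single-knockdown MCF7, -1.77 after siZFX and -1.73 after siBoth, with adjusted p of 1.75e-12, 1.47e-07, 1.84e-09 and 2.38e-10. ZNF711 (X chromosome, 84498997 to 84528368, plus strand) was a low gene in MCF7 and had no listed value in C42B. It stood at 3.467 ± 0.288 in 4-group control, 2.073 ± 0.293 after siZNF711 and 2.233 ± 0.2 after siBoth, or 59.8% and 64.4% of control. After siZFX alone ZNF711 was higher, at 5.226 ± 0.251, or 150.7% of control (log2 change 0.48 ± 0.103 SE, adjusted p = 0.00319). Its fall after siZNF711 passed in the fit of all 4 groups (-0.54, adjusted p = 0.0249) and not with only the 2 groups compared (adjusted p = 0.185). In single-knockdown MCF7, ZNF711 was 6.711 ± 1.01 after siZFX and 5.351 ± 0.593 in control (adjusted p = 0.105, and 0.0281 with the replicate number as a block).

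**Figure D1:**
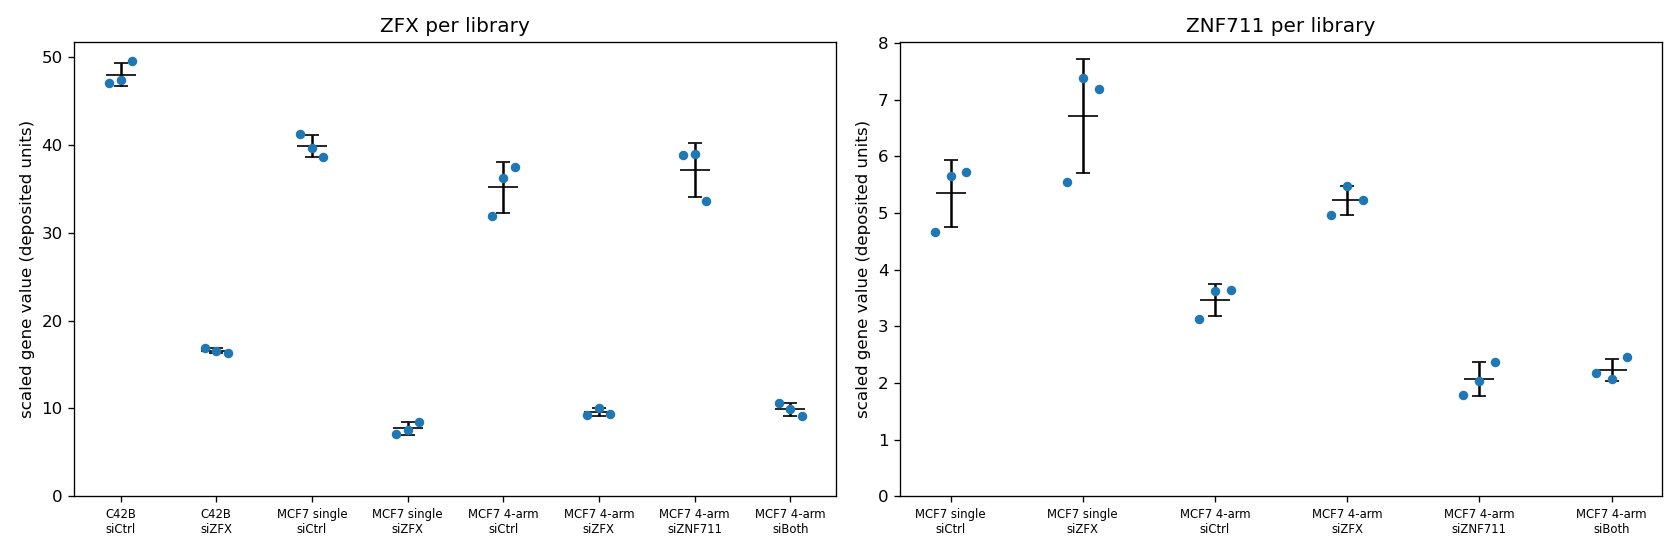
Scaled values of ZFX (left) and ZNF711 (right) in each library, in the authors' units, with groups along the horizontal axis; points are libraries, long horizontal marks are means and bars are SD (n = 3). ZFX stood between 7.729 and 16.58 on average in the groups that received its siRNA and between 35.16 and 47.98 in the others, and ZNF711 was highest in the siZFX groups of each MCF7 experiment.

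The C42B comparison asked which genes changed after siZFX in this prostate cancer line. The groups of the 3 experiments hold no rescue and no separate ZFX siRNAs. Effects of the siRNA pool beyond ZFX can therefore not be told apart. The largest falls were in the lysosomal protease gene CTSZ, the phosphatase subunit gene ANKRD52 and the BMP-binding protein gene TWSG1, and the largest rises in the heme oxygenase gene HMOX1 and the stress cytokine gene GDF15. CTSZ went from 56.97 ± 1.73 to 11.56 ± 0.563 (4.62-fold) and ANKRD52 from 89.83 ± 2.53 to 26.37 ± 1.12 (3.32-fold). HMOX1 went from 24.18 ± 1.92 to 220.8 ± 28.7 (8.78-fold) and GDF15 from 53.81 ± 1.13 to 226.2 ± 27.5 (4.13-fold). Genes of DNA replication and mitosis fell together, while genes of cholesterol synthesis, ribosomal proteins and mitochondrial respiration rose by small amounts, and as lists these passed camera with a preset but not with an estimated correlation (adjusted p from 0.346 to 0.497).

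Other genes with large falls in C42B were POMGNT1, a glycosyltransferase of O-mannosyl glycans (-1.65), the kinase gene TESK1 (-1.58), the ubiquitin ligase gene PELI3 (-1.49), the exosome nuclease gene DIS3L (-1.45), the zinc finger gene ZFP30 (-1.45), LONRF1 (-1.44) and TWSG1 (-1.81). Large rises on the log2 scale were seen for the prostaglandin reductase gene PTGR1 (1.64), the stress transcription factor gene ATF3 (1.61), the apoptosis inhibitor gene BIRC3 (1.53), the collagen receptor gene DDR2 (1.42), TP53INP1 (1.30) and ATXN1 (1.16). Rises of FTH1 (1.26) and MTRNR2L12 (1.25) are uncertain because these genes have near-identical copies elsewhere in the genome. Adjusted p for these genes ran from 4.08e-13 to 2.37e-05. In all, 5072 genes were higher and 4156 lower of 13846 tested, and 373 and 713 of them changed at least 1.5-fold. The median size of a called change was 0.292 on the log2 scale. With median-of-ratios scaling the split was 4244 higher and 4729 lower, so the balance of small rises and falls is not settled.

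All 20 tested members of the G1/S and DNA replication list fell in C42B, with a median log2 change of -0.504. They included the helicase subunit genes MCM3 (-0.76, from 137.1 ± 3.97 to 80.7 ± 3.45), MCM7 (-0.46) and MCM4 (-0.50) and the folate enzyme gene DHFR (-0.53). All 20 members of the G2/M and mitosis list fell as well (median -0.618), among them the kinesin genes KIF20A (-0.80, from 107 ± 1.54 to 61.02 ± 1.03) and KIF23 (-0.73), the centromere gene CENPF (-0.76) and the checkpoint kinase gene BUB1 (-0.69). Of 21 cholesterol synthesis genes 19 rose (median 0.271), led by HMGCS1 (0.71), FDFT1 (0.60), SC5D (0.56) and DHCR7 (0.45). Cytosolic ribosomal protein genes rose in 33 of 34 cases (median 0.249), with RPS18 at 0.53 and RPL5 at 0.31. Of the nuclear-encoded oxidative phosphorylation genes 21 of 24 rose and 1 fell, with COX6C at 0.42, and all 13 mitochondrially encoded genes rose, with MT-CO1 at 0.39. Among 20 lysosome genes 16 rose, such as NEU1 (1.10), SQSTM1 (0.91) and NPC1 (0.68), and 2 fell, of which CTSL changed by -0.84. Of 14 genes for endoplasmic reticulum (ER) chaperones and the unfolded protein response 11 fell, including PDIA4 (-0.65) and MANF (-0.53), while the ER-associated genes DNAJB9 (0.64) and HERPUD1 (0.51) rose. Of 8 immediate early genes 7 rose, with JUN at 0.88 and DUSP1 at 0.79, and 9 of 14 replication-dependent histone genes rose, with HIST2H2BE at 1.05. Counts adjusted over the list alone were identical for these 10 lists. The preset-correlation camera test set each of them apart from the other genes, with adjusted p of 3.72e-11 (G1/S), 9.45e-13 (G2/M), 1.49e-06 (cholesterol), 1.69e-09 (ribosomal proteins), 2.57e-05 (oxidative phosphorylation), 0.00127 (mitochondrially encoded), 0.000228 (lysosome), 0.00324 (ER), 0.00322 (immediate early) and 0.0178 (histones). None of the 10 passed when the correlation was estimated, with adjusted p of 0.346 to 0.497 with an estimated correlation.

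The other tested lists in C42B did not pass camera. Of 18 androgen response genes 9 rose and 5 fell (11 and 5 adjusted over the list alone), with SLC45A3 at -1.18, KLK2 at -0.58, HOXB13 at -0.46 and TMPRSS2 at 0.61 (camera adjusted p = 0.616). The p53 target list had 13 rises and 6 falls in 22 genes, including CDKN1A at 0.85 (adjusted p = 0.0827), and the ATF4 amino acid response list 10 rises and 2 falls in 17 (0.0722). Of 7 NF-kB genes 5 rose and 2 fell (0.14), and of 13 interferon genes 8 rose and 3 fell, with IFIT2 at 1.25 and OAS3 at -0.91 (0.251). IFIT2 was a low gene, at 0.9085 in control and 3.53 after siZFX. Rises and falls numbered 5 and 2 of 10 in the estrogen list (0.449), 5 and 4 of 13 in hypoxia (0.755), 6 and 6 of 15 in epithelial (0.989), and 2 and 1 of 6 in mesenchymal markers (0.797). They numbered 13 and 2 of 20 in ribosome biogenesis (0.0644), 9 and 2 of 14 in glycolysis (0.0722), 6 and 2 of 12 in core housekeeping (0.14), and 5 and 11 of 21 in the spliceosome (0.193). The spliceosome list held SF3B1, a component of the U2 particle, which fell by 1.04 on the log2 scale. In the remaining tested lists they numbered 13 and 4 of 20 for the proteasome (0.192), 6 and 4 of 14 for extracellular matrix remodelling (0.755), 9 and 8 of 22 for PI3K AKT MAPK components (0.711) and 7 and 6 of 19 for apoptosis regulators (0.989). Adjusted over the list alone, the counts were the same except 7 rises for epithelial, 10 for glycolysis and 6 for the spliceosome. Immune and endothelial markers had 2 tested members and intestinal markers 1, none of which passed in limma (smallest adjusted p 0.161 and 0.195). The medians of the hypoxia, PI3K and apoptosis lists lay just above 0 (0.009, 0.002 and 0.008) and turned negative with median-of-ratios scaling (-0.035, -0.041 and -0.035).

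In single-knockdown MCF7 the comparison asked the same of a breast cancer line. DIS3L, ANKRD52, LONRF1 and ZFP30 fell here too, and HMOX1, ATF3 and GDF15 again rose. Genes of the ATF4 amino acid response, ER chaperones, NF-kB signalling and the immediate early response rose nearly as whole lists, which passed camera with a preset but not with an estimated correlation (adjusted p of 0.269, 0.276, 0.276 and 0.276). DIS3L went from 21.3 ± 0.776 to 8.315 ± 0.331 (2.39-fold) and ANKRD52 from 244.8 ± 8.8 to 115.1 ± 8.77 (2.12-fold), while ATF3 went from 25.45 ± 1.14 to 54.76 ± 5.39 (2.10-fold) and HMOX1 from 44.93 ± 3.89 to 148.4 ± 40.4 (3.18-fold). Further falls on the log2 scale were GBAS, a mitochondrial protein gene (-1.14), LONRF1 (-1.13), the pyruvate dehydrogenase subunit gene DLAT (-1.03), the BBSome gene TTC8 (-1.02), ZFP30 (-1.02), ZNF32 (-0.99) and the actin regulator gene CYFIP2 (-0.98). Further rises were the immediate early gene IER3 (1.00), the growth factor gene HBEGF (0.93), the transcription factor gene BHLHA15 (0.91), the peptide hormone gene ADM2 (0.89), RASD1 (0.84), GDF15 (0.83) and the amino acid transporter gene SLC7A5 (0.81). CYP1B1 rose by 1.06 (from 210.7 ± 28.6 to 466.4 ± 218), and its call was lost without control replicate 1 (adjusted p = 0.0519) or 2 (0.0566).

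Of 16 ATF4 response genes 15 rose in single-knockdown MCF7 (median 0.625), including the pseudokinase gene TRIB3 (0.76), the stress factor gene DDIT3 (0.67) and CEBPB (0.64). Of 14 ER chaperone genes 13 rose (median 0.432), with HERPUD1 at 0.81, HSPA5 at 0.78, HYOU1 at 0.59 and CALR at 0.47. All 8 NF-kB genes rose (median 0.587), among them BIRC3 (0.80), ICAM1 (0.80), TNFAIP3 (0.60) and NFKB2 (0.55), and 12 of 14 immediate early genes rose, with JUN at 0.55 and DUSP1 at 0.53. Camera adjusted p was 2.06e-14, 1.18e-11, 1.04e-08 and 1.04e-08 for these 4 lists, and 0.269, 0.276, 0.276 and 0.276 with an estimated correlation. Smaller shifts were 8 rises of 21 for cholesterol synthesis (11 adjusted over the list alone), 7 of 15 for histones (8), 2 of 15 for interferon genes (2) and 5 of 20 for the lysosome (5), with camera adjusted p of 4.91e-05, 5.76e-05, 0.00197 and 0.0192. With an estimated correlation those adjusted p were 0.276, 0.615, 0.724 and 0.467. Of 13 mitochondrially encoded genes 2 fell, MT-ND6 (-0.26) and MT-ND5 (-0.18), and none when adjusted over the list alone (camera adjusted p = 0.0473, 0.0595 with median-of-ratios scaling, and adjusted p = 0.738 with an estimated correlation). G1/S genes had 1 rise, CDC6 (0.50), and 4 falls in 20 (adjusted p = 0.211), and in G2/M CENPF alone passed (-0.22, 0.63 for the list), where the list median of -0.009 turned to 0.010 with median-of-ratios scaling. In all, 1145 genes were higher and 1704 lower of 13698 tested, and 80 and 199 changed at least 1.5-fold. Replicate 1 of siZFX deviated more from its group (SD 0.145 on the log2 scale) than the other libraries of this experiment (0.067 to 0.096), and without it 2379 genes were higher and 2867 lower. The numbers were 682 and 1016 without control replicate 1, 448 and 784 without control 2, 573 and 968 without control 3, and 733 higher without siZFX replicate 2.

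The effects in C42B and single-knockdown MCF7 were also compared directly, through the difference of the log2 changes. CELSR2, CTSZ, LPGAT1, SOCS6 and TNFAIP2 had lower effects in C42B, and TP53INP1, HMOX1, GDF15 and YPEL2 higher ones. CELSR2, an adhesion cadherin gene, went from 35.72 ± 0.547 to 12.94 ± 0.289 in C42B and stood at 1011 ± 20.1 and 1005 ± 106 in MCF7 (difference -1.38 ± 0.079 SE, adjusted p = 9.15e-08). SOCS6, a cytokine signalling suppressor gene, went from 12.05 ± 1.31 to 3.583 ± 0.408 in C42B and stood at 22.74 ± 1.72 and 21.5 ± 3.4 in MCF7 (-1.42 ± 0.151). The differences were -1.62 for CTSZ, -1.15 for LPGAT1, -1.18 for TNFAIP2, 1.69 for TP53INP1, 1.46 for HMOX1, 1.22 for GDF15 and 1.21 for YPEL2. MTRNR2L12, an uncertain gene because of its copies, differed by 1.23. ZFX was reduced less in C42B (difference 0.75 ± 0.082, adjusted p = 1.28e-05). All 20 G2/M genes had a lower effect in C42B (median difference -0.58), with KIF20A at -0.73, KIF23 at -0.66, BUB1 at -0.59 and CDC20 at -0.86, and this list also passed camera with an estimated correlation (adjusted p of 2.86e-18 and 0.0301). G1/S genes were lower in 17 of 20 cases (-0.42), and ER chaperone genes in 12 of 14 (-0.679), with PDIA4 at -1.02, HSPA5 at -0.92 and HYOU1 at -0.88. Their camera adjusted p was 1.72e-11 and 8.99e-14, and adjusted p = 0.293 and 0.143 with an estimated correlation. Mitochondrially encoded genes were higher in 11 of 13 cases (13 adjusted over the list alone, adjusted p = 1.78e-05, and adjusted p = 0.408 with an estimated correlation). In all, 2409 genes had a higher and 1933 a lower effect in C42B of 13636 tested, and 1635 and 2472 with median-of-ratios scaling. Line, experiment and transfection reagent differ together, so the comparison cannot separate them.

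In the 4-group MCF7 experiment siZFX lowered TMEM189 and LRRC41 along with ANKRD52, DIS3L and LONRF1, and raised ATF3, HMOX1, RASD1, ICAM1 and SLC7A11. TMEM189, a plasmalogen synthesis gene named PEDS1 in the annotation, went from 152.1 ± 8.18 to 68.95 ± 1.88 (2.19-fold), and LRRC41 from 54.13 ± 2.48 to 24.46 ± 0.941 (2.17-fold). ATF3 went from 4.418 ± 0.97 to 12.45 ± 0.635 (2.51-fold) and HMOX1 from 20.13 ± 2.05 to 50.84 ± 8.66 (2.44-fold). Other large falls were the mitochondrial import gene TIMM17B (-1.25), DIRC2 (-1.10), LONRF1 (-1.03), RIN3 (-1.03), DIS3L (-1.02), the actin-bundling gene DMTN (-0.97) and ANKRD52 (-0.94). Other large rises were the cystine transporter gene SLC7A11 (1.15), the NF-kB inhibitor gene TNFAIP3 (1.11), the adhesion gene ICAM1 (1.07), RASD1 (1.04), the nuclear receptor gene NR4A3 (0.96), CYP1B1 (0.87), FKBP14 (0.82) and the chaperone gene DNAJB9 (0.80), with adjusted p from 4.64e-07 to 0.000539.

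Of 16 ATF4 response genes 14 rose after siZFX (median 0.358), with ASNS at 0.56 and DDIT3 at 0.68, and of 14 ER chaperone genes 12 rose (0.344), with HERPUD1 at 0.69, HSPA5 at 0.57 and DNAJB11 at 0.43. All 7 NF-kB genes rose (0.77), with BIRC3 at 0.96, RELB at 0.77 and NFKB2 at 0.56, and 9 of 14 immediate early genes rose (0.377), with JUN at 0.59 and KLF6 at 0.44. Camera adjusted p was 3.85e-11, 3.85e-09, 9.42e-09 and 2.65e-06, and 0.0535, 0.24, 0.071 and 0.0535 with an estimated correlation. Of 15 interferon genes 8 rose (11 adjusted over the list alone), with IRF7 at 0.42 and STAT1 at 0.25, and of 20 G2/M genes 9 rose (12), with TTK at 0.31 and TOP2A at 0.21. Of 21 cholesterol genes 7 rose (7), with HMGCS1 at 0.30. Camera adjusted p for these 3 lists was 5.79e-05, 0.000239 and 0.000752, with adjusted p = 0.347, 0.24 and 0.24 with an estimated correlation. Among 22 p53 targets 11 fell (13 adjusted over the list alone), with PHLDA3 at -0.52 and RRM2B at -0.32, and 4 rose, with GDF15 at 0.72 and SESN2 at 0.32 (adjusted p = 0.0154, and adjusted p = 0.24 with an estimated correlation). In the estrogen list 6 of 18 rose, with PDZK1 at 0.47 and TFF1 at 0.33, and 1 fell (adjusted p = 0.0238, and adjusted p = 0.347 with an estimated correlation). In all, 1850 genes were higher and 1879 lower of 14337 tested, and 53 and 172 changed at least 1.5-fold. Without control replicate 1 the higher count was 1129. The prostate marker KLK3, looked up after the values were seen, stood at 10.42, 2.716 and 0.7114 in the siZFX libraries, 1.618, 0.7255 and 0.9577 in control and 0.88, 0.9431 and 5.462 after siBoth.

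Set against each other, the siZFX effects of the MCF7 experiments differed past the threshold at few genes. How many smaller differences went uncalled was not measured. The effect on DDIT4 was lower in the 4-group experiment by 0.57, and so were those on BBC3 (-0.63), CACFD1 (-0.57), UNC5B (-0.53) and RABAC1 (-0.52), while those on DLAT (0.49), TOP2A (0.37) and ANLN (0.33) were higher. In all, 4 genes were higher and 15 lower of 13983 tested (2090 at an unadjusted p under 0.05 in limma). With the replicate number as a block 1 was higher and 3 lower, and of the 8 genes named here all but DDIT4 lost their call (adjusted p from 0.061 to 0.0899). The p53 target list had a lower effect in the 4-group experiment, with 1 gene lower (9 lower and 1 higher adjusted over the list alone, median -0.18), and passed camera with a preset (adjusted p = 0.000379) and an estimated correlation (0.0469). The G2/M list had a higher effect, with 1 gene higher (11 adjusted over the list alone, median 0.206, adjusted p = 5.43e-05, and adjusted p = 0.408 with an estimated correlation). Leaving out any 1 library except 4-group control replicate 3 moved a count by over 1.5 times, over a range of 0 to 21 higher and 0 to 48 lower.

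Across the 3 siZFX experiments, 790 of the 12089 genes tested in all of them were lower each time and 385 were higher each time, where independent lists would give 66.6 and 53.2. Apart from ZFX itself, the shared falls with the largest mean log2 change were ANKRD52 (-1.25), DIS3L (-1.24), LONRF1 (-1.20), TMEM189 (-1.17), ZFP30 (-1.12), LRRC41 (-1.09), TESK1 (-1.07), POMGNT1 (-1.04) and TWSG1 (-1.0). The shared rises were HMOX1 (2.03), ATF3 (1.33), GDF15 (1.20), PTGR1 (0.96), SLC7A11 (0.89), ICAM1 (0.79), DDIT3 (0.74), the uncertain FTH1 (0.73), the microtubule gene MAP1B (0.72) and the microRNA host gene MIR22HG (0.70). TWSG1 fell by 1.81 in C42B, 0.73 in single-knockdown MCF7 and 0.47 in 4-group MCF7 on the log2 scale, whereas SLC7A11 rose by 0.82, 0.71 and 1.15. A further 98 genes passed in all 3 with mixed directions. Log2 changes of C42B and single-knockdown MCF7 had a Pearson r of 0.533 and a Spearman rho of 0.487 over 12255 genes, those of C42B and 4-group MCF7 0.485 and 0.422 over 12349, and those of both MCF7 experiments 0.713 and 0.626 over 13406. These are correlations across genes, which are not independent replicates. Called genes moved in opposite directions in 211, 364 and 2 cases for the 3 pairs, where independent lists would give 887.1, 1178.2 and 386.2.

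**Figure D2:**
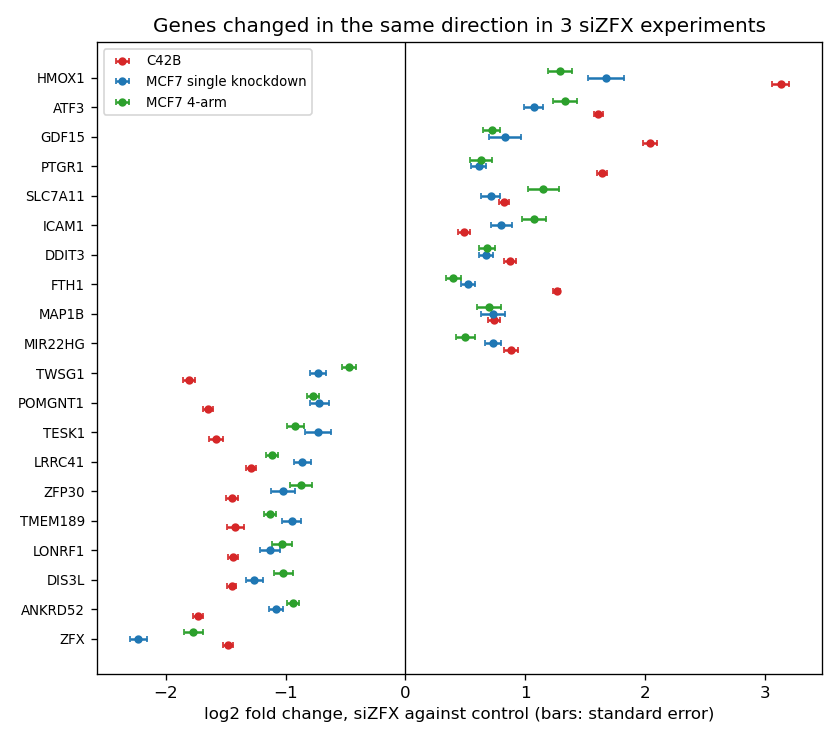
Log2 change after siZFX against control (horizontal axis) for the 20 genes with the largest mean change among those called in the same direction in all 3 experiments; points are fitted values and bars standard errors, coloured by experiment. HMOX1 lies furthest to the right in each experiment except 4-group MCF7, where ATF3 (1.33) exceeds it (1.29), and ZFX lies furthest to the left in both MCF7 experiments.

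Knockdown of ZNF711 alone in MCF7, which left ZNF711 at 59.8% of control, gave few called genes. Such a partial knockdown cannot show how many genes depend on ZNF711. The largest fall was in the lysine methyltransferase gene SETD7, SUMF1, which activates sulfatases, also fell, and the carbonic anhydrase gene CA2 rose. SETD7 went from 163.5 ± 9.89 to 97.46 ± 11.6 (1.68-fold), SUMF1 from 20.31 ± 0.978 to 13.1 ± 1.02 (1.51-fold) and CA2 from 122.7 ± 1.96 to 160.5 ± 7.25 (1.31-fold). Other falls on the log2 scale were the small GTPase gene RAB8B (-0.72), the cytokine receptor gene OSMR (-0.67), the homeobox genes MEIS2 (-0.58) and MNX1 (-0.45), TTF2 (-0.51), CDCA4 (-0.47), CEBPA (-0.46) and MTPN (-0.45). Other rises were ATF3 (0.52), NCEH1 (0.38), MANBA (0.36), NUCB2 (0.34), POC5 (0.34), PGM2L1 (0.34), SNIP1 (0.32) and HDHD2 (0.31), and NOMO3 (0.33), which is uncertain because of its near-identical copies. Single list members past the threshold were UHRF1 in the G1/S list (-0.30), CCND1 in the estrogen list (-0.25), CCNG1 among p53 targets (0.22) and SF3A3 in the spliceosome list (0.22). As a list, cholesterol synthesis genes lay above the other genes with none of 21 past the threshold in limma and 6 higher adjusted over the list alone, a median of 0.089 and a camera adjusted p of 1.95e-05. Lysosome genes (0 of 20, 2 adjusted over the list alone, median 0.083, adjusted p = 2.57e-05), proteasome genes (0 of 20 and 0, median 0.079, 0.000375) and ER chaperone genes (0 of 14, 4 higher and 1 lower adjusted over the list alone, median 0.119, 0.0004) also lay above. G1/S genes lay below (1 of 20 and 1, median -0.081, adjusted p = 0.000838). None held, with adjusted p = 0.471 for cholesterol and 0.707 for the other 4 with an estimated correlation. In all, 45 genes were higher and 53 lower of 14337 tested, and 2 and 6 changed at least 1.5-fold. At an unadjusted p under 0.05 in limma the number was 2176, so smaller changes may have gone uncalled. With only the 2 groups compared 2 were higher and 11 lower, and the calls of ATF3, CDCA4, CEBPA, HDHD2, MANBA, MNX1, NCEH1, NOMO3, NUCB2, PGM2L1, POC5 and SNIP1 were lost. Higher and lower counts were 8 and 22 without siZNF711 replicate 1, 273 and 343 without replicate 3, 6 and 24 without control 1, 4 and 18 without control 2, 135 and 119 without control 3, and 34 lower without siZNF711 replicate 2.

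After siRNA against ZFX and ZNF711 together, stress genes stood several-fold above control. RNA of ZFX stood at 28.2% and that of ZNF711 at 64.4% of control, so both knockdowns were partial. The siRNA amount of these libraries is not stated. A larger total amount can therefore not be told apart from the joint lowering of both factors. This limit also holds for siBoth against the single knockdowns and for the interaction below. ATF3 went from 4.418 ± 0.97 to 42.29 ± 2.54 (8.06-fold), TNFAIP3 from 7.301 ± 1.43 to 43.04 ± 2.87 (5.35-fold), DDIT3 from 10.21 ± 1.09 to 47.19 ± 2.97 (4.31-fold) and DNAJB9 from 31.01 ± 6.47 to 140.6 ± 7.83 (4.48-fold). The falls were led by ZFX, DMTN, TIMM17B and SAMD11. Genes of the ATF4, ER chaperone, NF-kB, immediate early and interferon lists rose nearly throughout, while most genes of DNA replication, ribosomal proteins and oxidative phosphorylation fell. Of these 8 lists only the ATF4 and immediate early lists passed camera with an estimated correlation, against adjusted p from 0.0571 to 0.697 for the others. Further rises on the log2 scale were RASD1 (2.29), NR4A3 (2.26), ICAM1 (2.13), GEM (2.09), SLC7A11 (2.09) and NR4A1 (2.08). Further falls were DMTN (-1.37), TIMM17B (-1.21), SAMD11 (-1.19), the lipoprotein receptor gene LRP3 (-1.18), RIN3 (-1.16), CYFIP2 (-1.14), LRRC41 (-1.13), DIRC2 (-1.12) and the serine protease gene HTRA1 (-1.12). Adjusted p for these genes ran from 1.38e-11 to 3.36e-07.

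All 16 ATF4 response genes rose after siBoth (median 1.024), with SESN2 at 1.10 and ASNS at 1.07. All 14 ER chaperone genes rose (0.805), with HERPUD1 at 2.0, HSPA5 at 1.49 and DNAJB11 at 0.83, as did all 7 NF-kB genes (1.586), with RELB at 1.59 and NFKB2 at 1.31. Of 14 immediate early genes 13 rose (1.094), with JUN at 1.78, DUSP1 at 1.59, KLF6 at 1.39 and ZFP36 at 1.13, and of 15 interferon genes 14 rose (0.914), with IRF9 at 1.40 and OAS1 at 1.39. Of 21 cholesterol genes 14 rose (0.216), with HMGCS1 at 0.65 and LDLR at 0.47, and of 15 histone genes 9 rose (10 adjusted over the list alone, 0.287), with HIST1H1E at 0.93. Of 20 G1/S genes 16 fell (-0.323), with E2F1 at -0.59, UHRF1 at -0.54 and MCM3 at -0.48, while CDC6 rose by 0.67. Of 34 ribosomal protein genes 24 fell (27 adjusted over the list alone, -0.199), with RPL35 at -0.52, and of 24 oxidative phosphorylation genes 20 fell (-0.261), with ATP5C1 at -0.47 and COX5B at -0.42. Counts adjusted over the list alone were otherwise identical for these 10 lists. Camera adjusted p was 5.44e-15 (ATF4), 5.44e-15 (ER), 1.34e-09 (NF-kB), 5.93e-12 (immediate early), 7.05e-09 (interferon), 1.17e-05 (cholesterol), 0.00162 (histones), 4.4e-05 (G1/S), 6.77e-05 (ribosomal proteins) and 0.000497 (oxidative phosphorylation). Only the ATF4 and immediate early lists held, with adjusted p = 0.0235 and 0.00634 with an estimated correlation, against adjusted p = 0.0907, 0.0571, 0.214, 0.119, 0.271, 0.431, 0.697 and 0.636 for the others in the order given. The p53 list had 6 rises, such as AEN (0.59), and 11 falls, such as DDB2 (-0.57), in 22 genes (adjusted p = 0.836). In all, 3055 genes were higher and 4289 lower of 14337 tested, and 521 and 532 changed at least 1.5-fold. With median-of-ratios scaling the split was 3657 higher and 3566 lower, and the medians of the estrogen (-0.009 to 0.039), ribosome biogenesis (-0.006 to 0.043), lysosome (-0.014 to 0.034), housekeeping (-0.047 to 0.002), proteasome (-0.035 to 0.014) and PI3K (-0.025 to 0.023) lists changed sign.

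**Figure D3:**
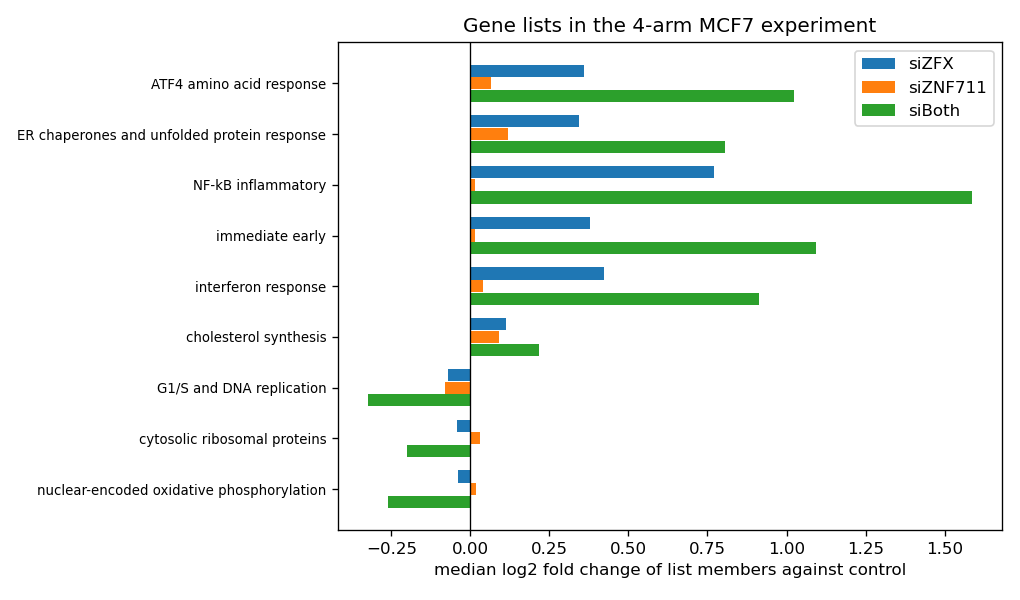
Median log2 change against control (horizontal axis) of the tested members of 9 gene lists in the 4-group MCF7 experiment, with 1 bar per knockdown; no error is drawn. The NF-kB bar reaches 1.586 after siBoth and 0.77 after siZFX, and the ATF4 bar 1.024 and 0.358.

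Beyond siZFX alone, siBoth raised DDIT3 (1.43), ATF3 (1.69), GEM (1.46), DNAJB9 (1.36) and TNFAIP3 (1.31) further and lowered CALML5 (-0.82), NPNT (-0.70), SUMF1 (-0.65), SEMA5A (-0.64) and CORO1A (-0.63). The ATF4 list was higher in siBoth than in siZFX in 14 of 16 genes, the ER list in 14 of 14, NF-kB in 7 of 7 and immediate early in 13 of 14, and these 4 lists held with an estimated correlation (adjusted p of 0.016, 0.0443, 0.0363 and 0.00199). ZFX was at the same level in these arms within the spread (difference 0.04 ± 0.077 SE, adjusted p = 0.742), and ZNF711 was lower in siBoth (-0.95, adjusted p = 1.18e-05). In all, 1637 genes were higher and 2443 lower in siBoth than in siZFX (2068 and 1442 with median-of-ratios scaling), and the lower count was 1462 without siBoth replicate 1, 1443 without siBoth 2 and 1587 without siZFX 3. Against siZNF711, siBoth was lower for ZFX (-1.81), DMTN (-1.23), DIS3L (-1.14) and HTRA1 (-1.14) and higher for ATF3 (2.49), TNFAIP3 (2.28), NR4A3 (2.18), RASD1 (2.10) and NR4A1 (2.09). RN7SL1 (-1.14) is uncertain because of its many copies. That comparison gave 2692 higher and 4150 lower genes, and 3340 and 3197 with median-of-ratios scaling. Between the single knockdowns, siZFX was lower than siZNF711 for ZFX (-1.85), DIS3L (-1.15) and TMEM189 (-1.14) and higher for HMOX1 (1.01), ICAM1 (1.01), SETD7 (0.98), TNFAIP3 (0.97) and SLC7A11 (0.94). The copy-rich RN7SL1 (-1.21) and RN7SL2 (-1.37) were also lower. It gave 1221 higher and 1574 lower genes, with 745, 787 and 811 higher without siZFX replicate 1, 2 or 3 and 805 with only these groups compared. The ATF4, NF-kB and immediate early lists were higher after siZFX in 12 of 16, 7 of 7 and 8 of 14 genes (13, 7 and 11 adjusted over the list alone) and held with an estimated correlation (adjusted p of 0.0417, 0.0417 and 0.0213).

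Most genes called after siZFX were called the same way after siBoth. Of 1879 genes lower after siZFX 1684 were lower after siBoth, and of 1850 higher 1445 were higher, where independent lists would give 562.1 and 394.2. The called rises had a median size of 0.244 after siZFX and 0.305 after siBoth, and the called falls 0.318 and 0.43. Across genes the log2 changes of siZFX and siBoth had r = 0.789, those of siZNF711 and siBoth 0.398 and those of siZFX and siZNF711 0.402, while 50 simulations of unchanged groups against the shared control gave r = 0.501. The covariances were 0.0575, 0.0174 and 0.0113, against 0.00551 simulated. The differences from it were 0.052, 0.0119 and 0.00579. In limma, 20 simulations of unchanged groups against the same controls gave at most 0 calls per contrast and 0 shared calls. How far the shared controls add to the overlap of genes that do change was not measured.

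The interaction asked whether siBoth differed from the sum of the separate effects on the log2 scale. DDIT3, NR4A1, GEM, NR4A3 and TNFAIP3 rose beyond that sum, and CA2, FAXDC2, MUCL1, EPHA7 and SYNC fell below it. DDIT3 stood at 10.21 ± 1.09 in control, 16.86 ± 0.294 after siZFX, 10.82 ± 0.514 after siZNF711 and 47.19 ± 2.97 after siBoth (interaction 1.35 ± 0.103 SE, adjusted p = 2.78e-06). CA2 stood at 122.7 ± 1.96, 128.9 ± 5.43, 160.5 ± 7.25 and 93.12 ± 2.49 in the same order (-0.85 ± 0.062, adjusted p = 2.09e-06). The interaction was 1.28 for NR4A1, 1.27 for GEM, 1.22 for NR4A3, 1.17 for TNFAIP3, -0.86 for FAXDC2, -0.72 for MUCL1, -0.64 for EPHA7 and -0.62 for SYNC. It was positive and past the threshold in 12 of 16 ATF4 genes (13 adjusted over the list alone), 13 of 14 ER genes (14), 7 of 7 NF-kB genes (7), 12 of 14 immediate early genes (14) and 5 of 15 interferon genes (12), with HERPUD1 at 1.04, HSPA5 at 0.66, SESN2 at 0.77, JUN at 1.11 and EGR1 at 1.06. It was negative in 10 of 20 G1/S genes (14 adjusted over the list alone), 8 of 34 ribosomal protein genes (17), 6 of 24 oxidative phosphorylation genes (12) and 6 of 14 glycolysis genes (10), with MCM6 at -0.36, RPL7A at -0.34, ATP5A1 at -0.35 and HK1 at -0.32. Camera adjusted p was 5.76e-17, 2.72e-18, 4.26e-13, 8.29e-20, 1.55e-08, 8.84e-06, 9.96e-08, 1.34e-06 and 8.23e-07 for these 9 lists in that order. With an estimated correlation the ATF4, NF-kB and immediate early lists held (adjusted p = 0.0167, 0.0228 and 0.000914), and adjusted p was 0.0547 for ER, 0.186 for interferon, 0.304 for G1/S, 0.365 for ribosomal proteins, 0.311 for oxidative phosphorylation and 0.186 for glycolysis. In all, 598 genes were higher and 827 lower of 14337 tested, and 821 and 368 with median-of-ratios scaling. The counts were 391 and 371 without siBoth replicate 1, and the lower count was 402 without siBoth 2, 496, 426 and 453 without siZFX 1, 2 or 3, 478 without control 2 and 547 without control 3.

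ZFX peaks lay at transcript starts in every cell type. Lists held 8708 peaks in C42B, 9039 in HCT116, 9955 in HEK293T, 9382 in MCF7 and 6905 in PrEC, and 4070 for ZNF711 in MCF7. The summit lay within 1000 bp of an annotated start for 88.5% of peaks in C42B (95% exact Clopper-Pearson interval 87.8 to 89.1), 90.3% in HCT116, 89.6% in HEK293T, 82.2% in MCF7 and 86.1% in PrEC, and for 68.5% (67.0 to 69.9) of ZNF711 peaks. Of the summits within that window, 71.6% (70.6 to 72.6) in C42B, 70.5% in HCT116, 70.3% in HEK293T, 69.0% in MCF7, 68.3% in PrEC and 70.3% (68.6 to 72.0) for ZNF711 lay downstream of the nearest start, against 52.8% (52.1 to 53.5) of 20000 random positions. The median position of these summits was 79 to 99 bp downstream of the nearest annotated start. Among summits within 1000 bp of a canonical start of a protein-coding gene, the median was 179 to 207 bp downstream. The peak with the highest score of the authors lay in INO80D, a chromatin remodelling gene, in all 6 lists. In C42B it spanned 206949541 to 206951210 on chromosome 2 (hg19), in an intron 363 bp downstream of the canonical start, with a fold enrichment of 143.8. Other leading peaks lay in the HECTD1 untranslated region (chromosome 14, 31675785 to 31677789, C42B), a FBXW4 intron (chromosome 10, 103453451 to 103455575, C42B), a SELENOT intron (chromosome 3, 150320734 to 150322016, HCT116), a PSMD6 coding exon (chromosome 3, 64008121 to 64009477, MCF7) and the INTS2 untranslated region (chromosome 17, 60004517 to 60005616, MCF7). For ZNF711 the leading peaks after INO80D lay in introns of PCBP2 (chromosome 12, 53845576 to 53846911) and of ZFX itself (X chromosome, 24166987 to 24168637, summit 203 bp downstream of its start). HEK293T peaks were wide (median 2152 bp, against 831 to 1133 bp in the other lists).

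**Figure D4:**
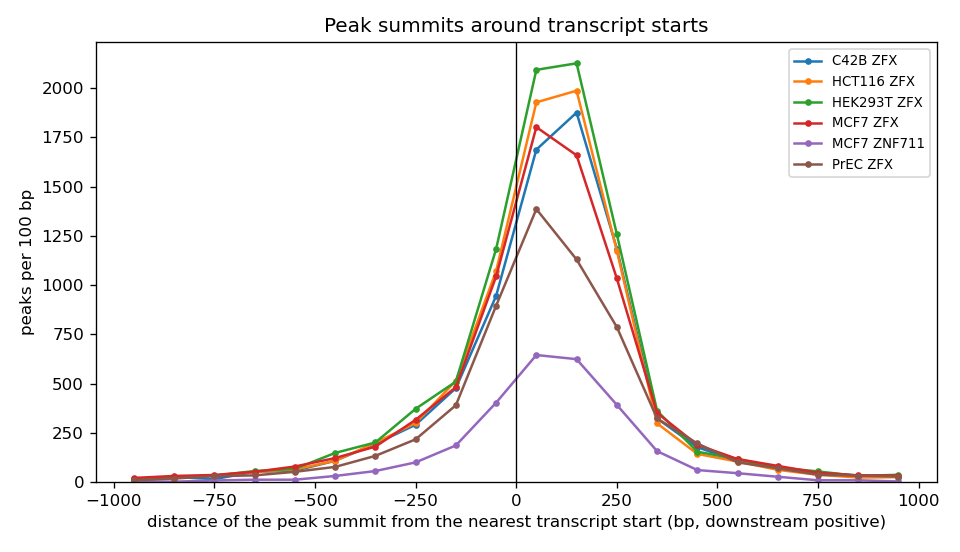
Number of peak summits per 100 bp (vertical axis) by distance from the nearest annotated transcript start in bp (horizontal axis, downstream positive), with 1 line per peak list. Each line is highest just downstream of the start, where 68.3% to 71.6% of the summits within 1000 bp lie downstream.

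By an overlap of at least 1 bp, most ZFX peaks were shared between cell types and most ZNF711 peaks with ZFX in MCF7. Of the C42B ZFX peaks 6639 (76.2%, 75.3 to 77.1) overlapped a MCF7 ZFX peak by at least 1 bp, and 60.3% (59.2 to 61.3) a PrEC peak. In the other direction, 69.8% (68.9 to 70.8) of MCF7 and 74.2% (73.1 to 75.2) of PrEC peaks overlapped C42B peaks. Of 4070 ZNF711 peaks 3005 (73.8%, 72.5 to 75.2) overlapped a ZFX peak in MCF7, whereas 33.3% (32.4 to 34.3) of MCF7 ZFX peaks overlapped a ZNF711 peak. These pairs were chosen after the values were seen. Of 19202 protein-coding genes 7611 had a ZFX peak summit within 1000 bp of a start in C42B and 7617 in MCF7, with 6542 in both, where independent sets would give 3019.1. For ZNF711 the number was 2983, of which 2951 (98.9%) also had a ZFX summit in MCF7. The share with a ZFX summit was 96.2% in C42B, 95.9% in HCT116, 96.1% in HEK293T and 94.1% in PrEC. A high share was thus not particular to MCF7. ZFX summits in all 5 cell types marked 4675 genes. Intervals cover counting error only, and each list is a single set, so no spread between replicates can be given. The lowest -log10 q in a ZFX list was 7.31 in PrEC, 9.55 in C42B, 9.97 in MCF7, 21.72 in HCT116 and 85.63 in HEK293T. A site absent from 1 list may therefore lie below the limit of that list. The samples hold no input of PrEC.

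Genes lowered by ZFX knockdown carried promoter ZFX peaks more often than other tested genes. In C42B 76.5% of the lower genes had one, against 55.3% of genes that did not pass (odds ratio 2.62, 95% interval 2.38 to 2.89, 2-sided Fisher's exact test, adjusted p = 5.82e-87). The shares were 76.3% and 58.1% in single-knockdown MCF7 (odds ratio 2.31, 2.05 to 2.61, adjusted p = 2.36e-45) and 78.0% and 55.4% in 4-group MCF7 (2.85, 2.53 to 3.21, adjusted p = 4.64e-75). Higher genes had ZFX peaks less often than genes that did not pass, at 50.7% in C42B (odds ratio 0.831, adjusted p = 3.17e-05), 42.9% in single-knockdown MCF7 (0.542, adjusted p = 2.18e-21) and 51.6% in 4-group MCF7 (0.858, adjusted p = 0.00447). Within strata of expression these odds ratios were 0.467, 0.377 and 0.502. Each of the 10 leading shared falls had a ZFX peak in C42B and MCF7, but these include ZFX, the siRNA target itself. The others ran from ANKRD52 and DIS3L to TWSG1. Of the 10 leading shared rises DDIT3 and FTH1 had such peaks in both lines. ZNF711 peaks also marked genes lowered by siZFX in MCF7, at 46.0% against 21.2% in the single-knockdown experiment (odds ratio 3.16, adjusted p = 6.03e-90) and 44.6% against 20.2% in the 4-group experiment (3.19, adjusted p = 2.29e-97). Among the genes lowered by siZNF711, 32.0% had a ZNF711 peak and 70.0% a ZFX peak, against 22.9% and 58.0% of genes that did not pass (odds ratios 1.59, 0.874 to 2.88, and 1.69, 0.924 to 3.1, adjusted p = 0.146 and 0.136). After siBoth 68.1% of lower genes had a ZFX peak against 51.6% (odds ratio 2.01, adjusted p = 4.07e-61), and 57.2% of higher genes (1.25, adjusted p = 1.05e-06), where the latter turned to 0.81 within strata of expression. In all, 18 such tests were made and adjusted together.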

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

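The tests of C42B scaling, of the MCF7 library that stood apart, of the siRNA amount and of other splits of the samples were chosen after the result was seen, and so were the 4 stress lists weighed together here. Each difference below was picked out because a direct limma test found that 2 effects differed.

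The interaction in the 4-group MCF7 experiment passed for 598 genes above and 827 below the sum of the separate effects, and for 821 and 368 with median-of-ratios scaling, so the balance turned round. Genes above were DDIT3 (1.35), NR4A1 (1.28), GEM (1.27), NR4A3 (1.22) and TNFAIP3 (1.17), and genes below were FAXDC2 (-0.86), CA2 (-0.85), MUCL1 (-0.72), EPHA7 (-0.64) and SYNC (-0.62). Of 100 splits of the 12 libraries, the real one included, 6 gave at least the real 1425 genes, and the highest other gave 3116. This count can neither exclude chance nor show it, because such splits can carry the siZFX effect itself. The 5 others as large were among 13 with 5 of the 6 siZFX and siBoth libraries on 1 side of the contrast. The median over those 13 was 1 gene. Splits with 3 on a side, as in the real one, or 4 (38 and 48) gave at most 3 genes.

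The excess in the stress lists is the first pattern weighed. Over the 51 members of the ATF4, ER chaperone, NF-kB and immediate early lists the median interaction was 0.547, with median changes of 0.39 after siZFX, 0.053 after siZNF711 and 1.055 after siBoth. Scaling of the siBoth libraries as the whole cause is argued against by a median of 0.6 with median-of-ratios scaling, and a single deviant library by a lowest median of 0.453 over the fits without 1 library. A larger total siRNA amount in the siBoth arm cannot be told apart from an effect of lowering both factors together. The amount is stated for 0 of these libraries, and no arm with matched non-targeting siRNA was analysed here. A joint effect of both factors may therefore be proposed only as a hypothesis.

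The siZFX effect was higher in C42B than in single-knockdown MCF7 for 2409 genes and lower for 1933, and this balance turned round with median-of-ratios scaling (1635 and 2472). The differences were 1.69 for TP53INP1, 1.46 for HMOX1, 1.23 for the uncertain MTRNR2L12, 1.22 for GDF15, 1.21 for YPEL2 and 0.75 for ZFX, and -1.62 for CTSZ, -1.42 for SOCS6, -1.38 for CELSR2, -1.18 for TNFAIP2 and -1.15 for LPGAT1. Of 100 splits drawn within each line, the real one included, 5 gave at least the real 4342 genes, and the highest other gave 7663. This count can neither exclude chance nor show it either, because such splits can carry a siZFX effect. The others with as many genes all kept the C42B siZFX and control libraries apart, so they carry the siZFX effect of C42B itself, and the highest swapped the groups of MCF7.

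More genes passed in C42B than in single-knockdown MCF7, and this is the second pattern weighed. Over 12255 genes tested in both, 8529 passed in C42B and 2493 in MCF7, a ratio of 3.42. With the MCF7 spread in place of its own, C42B still had 5918, a ratio of 2.37, so the smaller C42B spread may account for part but not for the whole. Without MCF7 siZFX replicate 1 the MCF7 count over all its genes was 5246 against 9228 in C42B, and with median-of-ratios scaling C42B still had 8973. A biological difference between the lines stays open and untested, since line, experiment and transfection reagent change together.

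Between the MCF7 experiments the siZFX effect was higher in the 4-group experiment for 4 genes and lower for 15. The differences were 0.49 for DLAT, 0.37 for TOP2A and 0.33 for ANLN, and -0.63 for BBC3, -0.57 for DDIT4, -0.57 for CACFD1, -0.53 for UNC5B and -0.52 for RABAC1. With the replicate number as a block only 1 gene was higher and 3 lower, and all of these 8 genes but DDIT4 lost their call. Of 100 splits drawn within each experiment, the real one included, 10 gave at least the real 19 genes, and the highest other gave 5366. Here too the count can neither exclude chance nor show it, because such splits can carry a siZFX effect. The others with as many genes all kept siZFX and control apart in at least 1 experiment, so they carry the siZFX effect itself, and the highest swapped the groups of the single-knockdown experiment.

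For each contrast of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. As many genes as the real split came from 1 split, the real one, for siZFX in C42B (9228, highest other 0), single-knockdown MCF7 (2849, highest other 0) and 4-group MCF7 (3729, highest other 0). The same held for siBoth against control (7344, highest other 1), siZFX (4080, highest other 0) and siZNF711 (6842, highest other 0), and for siZFX against siZNF711 (2795, highest other 0). For siZNF711 against control 2 splits gave as many genes as the real 98. The other was the split that put siZNF711 replicate 3 with control replicates 1 and 2, which gave 467, several times the real count, and points to a structure of these samples. That library deviated most from its group in the 4-group experiment (SD 0.141 on the log2 scale, against 0.094 to 0.113 for the others).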

How the results depend on the processing

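The alternative pseudocount, canonical transcripts, and strata of length and of GC and CpG content were chosen after seeing the data. Leaving out each library gave these ranges of genes higher and lower: 4632 to 4883 and 3756 to 4027 for C42B, 448 to 2379 and 784 to 2867 for single-knockdown MCF7, 1129 to 1852 and 1306 to 1891 for siZFX in 4-group MCF7, 4 to 273 and 18 to 343 for siZNF711, and 2545 to 2977 and 3659 to 4151 for siBoth. The ranges were 1174 to 1494 and 1443 to 2356 for siBoth against siZFX, 2282 to 2653 and 3392 to 3970 for siBoth against siZNF711, 745 to 1218 and 1111 to 1492 for siZFX against siZNF711, 391 to 700 and 371 to 1079 for the interaction, 1850 to 3183 and 1610 to 2528 for C42B against MCF7, and 0 to 21 and 0 to 48 for the MCF7 experiments against each other. The libraries behind moves of over 1.5 times were siZFX replicate 1 (2379 and 2867) and 2 (733 higher) and controls 1 (682 and 1016), 2 (448 and 784) and 3 (573 and 968) in single-knockdown MCF7, and control 1 for siZFX in 4-group MCF7 (1129 higher). For siZNF711 they were siZNF711 1 (8 and 22), 2 (34 lower) and 3 (273 and 343) and controls 1 (6 and 24), 2 (4 and 18) and 3 (135 and 119). They were siBoth 1 (1462 lower) and 2 (1443) and siZFX 3 (1587) for siBoth against siZFX, siZFX 1, 2 and 3 (745, 787 and 811 higher) for siZFX against siZNF711, and siBoth 1 (391 and 371), siBoth 2 (402 lower), siZFX 1, 2 and 3 (496, 426 and 453) and controls 2 and 3 (478 and 547) for the interaction. For the MCF7 experiments against each other each library but 4-group control 3 did so. With only the 2 groups compared, siZNF711 gave 2 higher and 11 lower genes, and siZFX against siZNF711 805 higher, from fits with fewer samples. Median-of-ratios scaling gave 1442 lower genes for siBoth against siZFX and 368 lower for the interaction (821 higher), turned the balance of C42B against MCF7 to 1635 higher and 2472 lower, and no filter gave 2 and 6 for the MCF7 experiments against each other. The cause was not tested. With the replicate block that last comparison gave 1 and 3, single-knockdown MCF7 gave 1439 and 1995, and ZNF711 passed there (adjusted p = 0.0281 in limma), while it moved no other count by over 1.5 times. Same-numbered libraries correlated at -0.11 to 0.07 in C42B and -0.19 to 0.17 in 4-group MCF7 and were not paired. Named genes kept their side of the threshold in 974 cases and lost it in 53 with median-of-ratios scaling, lost it in 21 with no filter, 6 with the pseudocount of 0.25, 18 with the block and 35 with only the 2 groups, and lost it in 700 and kept it in 6788 cases in fits without 1 library. ZFX, which did not differ, changed sign in siBoth against siZFX without siBoth 1 (-0.01, against 0.09 without siBoth 3) and in the interaction with median-of-ratios scaling (0.01), without siBoth 3 (0.01) and without control 1 (0.03). Of the camera calls 17 held and 102 were lost with an estimated correlation, and 99 held and 20 were lost with fry, which asks another question.

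Peak overlaps fell where 50% of both peaks had to be shared, and went up or down in the top 50% of the lists by score. These gave in turn 70.4% and 77.7% for C42B in MCF7, 65.4% and 71.9% for MCF7 in C42B, 26.7% and 35.0% for MCF7 ZFX in ZNF711 and 61.4% and 80.4% for ZNF711 in MCF7 ZFX. C42B in PrEC gave 52.8% and 59.8%, and PrEC in C42B 66.5% and 74.6%. For HEK293T, whose peaks were wide, the share of C42B peaks that overlapped went from 83.0% to 29.8% under the 50% rule. In the other direction the share went from 67.4% to 26.1%. Shares of summits near a start were, for 500 bp, 2000 bp, the top 50%, protein-coding genes and canonical transcripts in turn, 83.4%, 90.3%, 96.0%, 83.5% and 77.1% in C42B, 85.5%, 92.1%, 95.6%, 84.9% and 78.0% in HCT116, 84.5%, 91.6%, 96.1%, 83.7% and 76.9% in HEK293T, 76.5%, 85.2%, 92.2%, 76.7% and 69.9% in MCF7, 65.2%, 70.2%, 81.6%, 65.1% and 61.2% for ZNF711, and 80.2%, 89.1%, 91.4%, 81.0% and 73.7% in PrEC. Shares downstream moved in the top 50% to 72.9% in C42B, 71.8% in HEK293T, 70.6% in MCF7 and 70.0% in PrEC, with protein-coding genes to 70.0% in C42B, 68.9% in HCT116, 68.5% in HEK293T and 66.5% in MCF7, and with canonical transcripts to 81.2% in C42B, 79.7% in HCT116, 78.5% in HEK293T, 77.5% in MCF7, 81.8% for ZNF711 and 78.8% in PrEC. Odds ratios of peaks at higher genes turned within strata of expression to 0.608 (ZFX, siZNF711), 0.822 (ZNF711, siZNF711), 0.81 (ZFX, siBoth) and 0.851 (ZNF711, siBoth), and with transcript GC strata to 0.985 (ZFX, siZNF711). For ZNF711 peaks the ratio turned to 0.989 at genes lower after siZNF711 in the top 50%, and at genes higher after siBoth it no longer passed in the top 50% (1.14) or within transcript GC (1.03), length (1.03) and promoter CpG strata (1.09, and 1.09 for ZFX peaks). The cause was not tested. The planned DESeq2 tests of the 11 contrasts and of peaks at changed genes were not run, because the files hold no counts. Depth is unknown, so no limit from it can be given.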

Other observations

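The strata of length and of GC and CpG content and the lookups of KLK3 and KLK2 were chosen after the data were seen, and all strata and the hexamer and line-specific peak tests were written down before their own results were seen.

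Some genes moved alike in several knockdowns. SF3B1, a spliceosome component, fell by 1.04 in C42B, 0.75 in single-knockdown MCF7 and 0.50 in 4-group MCF7 on the log2 scale after siZFX, and by 0.24 after siBoth. The laminin genes LAMC2 and LAMA3 rose after siZFX in C42B (1.49 and 0.45), single-knockdown MCF7 (0.49 and 0.54) and 4-group MCF7 (0.42 and 0.67). In C42B LAMC2 was a low gene, at 0.6616 in control and 3.682 after siZFX. The lysosomal sialidase gene NEU1 and the autophagy receptor gene SQSTM1 rose too, by 1.10 and 0.91 in C42B, 0.44 and 0.56 in single-knockdown MCF7 and 0.30 and 0.34 in 4-group MCF7. The hexokinase gene HK2 rose in MCF7 after siZFX (0.44 and 0.57) and siBoth (0.63), while PGAM1 (-0.30), PFKL (-0.31) and TPI1 (-0.26) of the same glycolysis list fell after siBoth. The cyclin gene CCND1 rose in C42B after siZFX (0.61) and fell in MCF7 after siZNF711 (-0.25) and siBoth (-0.39). The siZFX effect on CCND1 differed between C42B and single-knockdown MCF7 by 0.68 (adjusted p = 5.52e-07 in limma).

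Promoters with a ZFX peak were mostly rich in CpG. Among 7030 genes with a peak at the canonical start in C42B 87.4% (86.6 to 88.2) had a CpG-rich promoter, and the shares were 87.3% in HCT116, 86.3% in HEK293T, 86.2% in MCF7, 88.5% in PrEC and 89.9% for ZNF711, against 57.8% of all 18922 genes. A CpG-rich promoter had a GC share of at least 0.55 and an observed over expected CpG of at least 0.65 within 500 bp of the start. The background of all genes was not limited to expressed ones. It therefore does not set promoters with a peak against those of other expressed genes.

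The higher share of promoter ZFX peaks at genes lowered by siZFX is the last pattern weighed. Expression level, GC content and length of the transcript, and GC and CpG content of the promoter were each stratified separately. Each of these properties alone as the whole cause is argued against by Mantel-Haenszel odds ratios over 10 strata. The lowest lower 95% bounds in the 3 experiments were 1.78, 2, 1.98 and 1.8. No strata joined these properties, so their combination as the cause was not tested and stays open. Direct activation by ZFX at these promoters may be a candidate explanation, as a hypothesis. The data hold no test of whether a peak acts on its gene, and many genes with a peak did not change.

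A hypothesis was that the hexamer AGGCCT marks the summits. It lay within 100 bp of the summit in 22.3% of C42B, 21.8% of HCT116, 19.2% of HEK293T and 23.4% of MCF7 ZFX peaks and 19.0% of ZNF711 peaks, against 7.9%, 7.9%, 7.6%, 7.5% and 6.6% of windows 500 bp away. The lowest ratio over the ZFX lists was 2.55, and the highest ratio of the other palindromic hexamers of the same composition without CpG was 1.8.

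A further hypothesis was that genes with a promoter ZFX peak in 1 line alone fall further in that line. The median difference of the siZFX effects (C42B minus single-knockdown MCF7) was -0.027 for 965 genes with a peak in C42B alone, 0.078 for 899 with a peak in MCF7 alone and 0.014 for 6500 with a peak in both. The difference of the first pair of medians was -0.105 (permutation test with 100000 permutations, p = 1e-05, the smallest they can give). Genes are not independent replicates, and the expression level in each line was not taken into account. The log2(value + 1) scale understates the change in a line where a gene is low.

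The prostate markers KLK3 and KLK2 were seen at low levels in some MCF7 libraries. KLK3 stood at 10.42 in replicate 1 and 2.716 in replicate 2 of siZFX and at 5.462 in replicate 3 of siBoth in the 4-group experiment, and between 0.7114 and 1.618 in the others. KLK2 stood at 2.507 in siZFX replicate 1 and 1.482 in siBoth replicate 3. In C42B, KLK3 stood at 2065, 2024 and 2073 after siZFX and at 2405, 2362 and 2293 in control. Whether the low MCF7 values are expression or carry-over between libraries was not tested.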
